A study of Mus musculus with 4 samples.

How the data were processed

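Poly(A) RNA from mouse trigeminal ganglia was fragmented, copied with random hexamer primers and sequenced on Illumina instruments as paired reads, per the labels' protocols. The design was 2 WT and 2 K823R libraries, grouped by sample title. The submitters' processing notes name fastp 0.19.5, HISAT2, RSEM and edgeR, and the genome build GRCm38.p6, without saying what each did. Annotation release, filters and strand setting are not given in the sources used here. The deposited table holds TPM, transcript abundances scaled to one total, for each of the 4 libraries, with 2 further columns that equal the authors' mean TPM of each group and were not used. The TPM columns each sum to 1000000 after rounding, which was checked on the file. The deposited gene length column was used for a check of length.

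TPM divides each gene's reads by its length and by the library's total, so an abundant transcript in one library lowers all others there, and read depth cannot be recovered. No counting interval or detection floor is given for that reason. A value of 0 can be a failed estimate in such a table, so genes at 0 are described as listed at 0, without a fold. If RSEM gave the values, reads that match several genes were divided by estimation, which would leave near-identical copies uncertain. Copies were searched for with BLAST 2.17.0 (at least 95% identity over 90% of the transcript). The search covered Trpv1, Hrh1, Gm43110 and the genes with the next smallest p in each direction. It also covered the loci listed at 0 that have a reference transcript, and genes matched to them. Most other list and pathway members named below were not searched. Of the 56035 gene rows, 55487 carried Ensembl identifiers and 548 were unnamed assembled loci. GENCODE M21, on GRCm38, matched 55141 identifiers, and its names were equal to those in the table for 96.7% of them. Coordinates come from that annotation.

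The plan made before the data were examined was a count test, with a written fallback to limma on log2(TPM + 1) if only TPM was given, and the fallback was used. Genes with a mean of at least 1 TPM over the 4 libraries were kept (15390, of which 13374 are protein-coding), and differences are K823R minus WT on the log2(TPM + 1) scale, which understates the change of low genes. The limma 3.58.1 test in R 4.3.3 used a variance trend and all 4 libraries, was two-sided, and was Benjamini-Hochberg adjusted with a threshold of 0.05. The prior gave 2.67 degrees of freedom in addition to the 2 residual ones. For the 9100 genes with a mean of at least 10 TPM the median SE of a log2 difference was 0.102 and the median half-width of its 95% interval was 0.268. A permutation test of a single gene with 2 libraries against 2 cannot give an exact p under 0.333, so single-gene p-values come from limma alone.

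Gene lists for neurons, glia, other cell types, neighbouring tissues and pathways, 40 in all, were fixed before the data were examined, and the 35 with at least 5 tested members were tested. The main list test was limma's camera with a preset correlation of 0.01 between genes, adjusted over the 35 lists. Beside it stand camera with an estimated correlation and fry. With an estimated correlation camera rests on the 2 residual degrees of freedom, so it could hardly call any list in this design. Named genes were chosen by a rule also fixed beforehand. It took Trpv1 and Hrh1 always, then genes past the threshold with both K823R libraries on one side of both WT libraries, then those with the smallest p in each direction up to 6, said not to have passed, and up to 4 members with the smallest p from each list. Predicted or unnamed genes, 6 on the higher side and 16 on the lower, were left out of the fill and only counted. Some genes that the rule would have named are not reported here.

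The gene test and the list test were checked on 20 simulated data sets of the 15390 genes with 50 genes changed at each fold size, in which a mean of 5.8 unchanged genes passed. The changed genes were drawn from those with a mean of at least 10 TPM, and the genes' spreads were shuffled among all genes. A list shifted by 0.5 on the log2 scale was found in 100% of the simulations, with a mean of 0.1 other lists called, for genes simulated as independent. The alternatives set beforehand and run were a pseudocount of 0.1 TPM, no filter, standard symbols only, a replicate block, leaving out each library, other thresholds, and the other list tests. Those that need counts (the edgeR normalizations, exact test and treat, DESeq2, voom and filters in CPM) were not run, because the table holds TPM. Rescaled TPM, quantile normalization, TPM filters, limma's treat and camera on preranked statistics were added in their place after the data were seen. Permutation and Fisher's exact tests used scipy 1.17.1, tables pandas 2.3.3 in Python 3.11.15, and plots matplotlib 3.10.9.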

Results

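RNA was sequenced from the trigeminal ganglion, the body of sensory neurons and glia that serves the face, of male C57BL/6 mice at 8 weeks of age. One group carried the K823R allele of Trpv1, in which the codon for a lysine was replaced by one for arginine, and the other group was wild-type (WT) littermates. TRPV1 is a cation channel of nociceptors opened by heat and capsaicin, and SUMOylation is the attachment of the small protein SUMO to a lysine of another protein. The comparison addresses whether the ganglion's transcripts differ when this lysine is lost, in a series concerned with TRPV1 SUMOylation, itch and H1 histamine receptors. Each group had 2 libraries, and the labels used here do not say how many animals stand behind each one. The p-values therefore measure only the spread between these samples, which may be technical.

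The deposited values are TPM, a transcript abundance scaled to the same total in every library, for 56035 gene rows. TPM keeps no read total, so the depth of each library is unknown. The 4 libraries listed between 21838 and 22119 genes above 0 and between 15131 and 15371 genes at 1 TPM or more. Mitochondrially encoded genes held 6.12% and 6.88% of the TPM in WT and 6.09% and 6.28% in K823R, and the 10 most abundant genes held 9.89% to 11.3%. Across the 15390 genes tested, the WT libraries correlated with each other at Pearson's r = 0.969 and the K823R libraries at 0.968. Libraries of different groups correlated at 0.965 to 0.969, and genes are not independent replicates. Of the Y-linked and X-inactivation list, Ddx3y, Eif2s3y, Kdm5d and Uty had at least 3.16 TPM in every library and Xist at most 0.01 TPM.

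The transcript that carries the codon change differed between the genotypes by less than the spread between replicates. Trpv1 (ENSMUSG00000005952) was at 34.9 ± 6.05 TPM in WT and 38.0 ± 4.18 TPM in K823R (SD, n = 2 each). The log2 difference was 0.12 with a standard error (SE) of 0.15 and a 95% confidence interval of -0.28 to 0.53 (limma, adjusted p = 0.938). Hrh1 (ENSMUSG00000053004), the Gq-coupled H1 histamine receptor, was scarce at 1.53 ± 0.304 TPM in WT and 1.95 ± 0.0707 TPM in K823R (SD, n = 2 each). Its log2 difference was 0.23 with SE 0.22 and a 95% confidence interval of -0.35 to 0.81 (limma, adjusted p = 0.932). Both K823R libraries lay above both WT libraries for Hrh1, and chance sets the groups apart in one direction or the other for 33.3% of genes. In GRCm38, Trpv1 lies on the plus strand of chromosome 11 from 73234292 to 73261242, and Hrh1 lies on chromosome 6 from 114397936 to 114483296. The codon of the K823R change occupies positions 73260454 to 73260456 in exon 16 of the transcript that encodes a protein of 839 residues. The codon itself was not analysed here, because TPM values hold no sequence. The sign of the Trpv1 difference rested on WT replicate 2, without which it was -0.048 (adjusted p = 0.962, in a range of 0.656 to 1 over the alternatives). It was 0.30 without WT replicate 1, 0.015 without K823R replicate 1 and 0.23 without K823R replicate 2. The Hrh1 difference was 0.35 without WT replicate 1, 0.11 without WT replicate 2 and 0.35 with a pseudocount of 0.1 TPM.

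Across the transcriptome, 1 of the 15390 genes tested passed limma at an adjusted p below 0.05, with 1 higher and 0 lower in K823R. That gene was Gm43110 (ENSMUSG00000105081), a processed pseudogene of 226 bases on the minus strand of chromosome 5 from 22472767 to 22472992. It was listed at 0 in both WT libraries and stood at 40.5 and 51.5 TPM in the K823R libraries (adjusted p = 0.0140). At least 90% of its transcript sequence matches a stretch of a Get4 transcript at 100% identity, so reads from that stretch can be assigned to either. Get4, which encodes a factor for the insertion of tail-anchored membrane proteins, was at 76.5 ± 8.04 TPM in WT and 68.2 ± 3.56 TPM in K823R (SD, n = 2 each; limma adjusted p = 0.918). By limma, 732 genes (4.76%) had an unadjusted p under 0.05. For 5229 genes (34.0%) the libraries of the groups did not overlap, against 33.3% by chance. Of all genes tested 57.4% were higher in K823R, with a median log2 difference of 0.026. These values are the background for the member counts and list medians below. The call on Gm43110 was lost without any one of the 4 libraries (adjusted p from 0.0915 to 0.146) and with no filter on low values (0.218). Over the alternatives without a replicate block it ranged from 0.00535 to 0.218.

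Among genes with a standard symbol, those with the next smallest p in each direction did not pass the test. Predicted or unnamed genes with p as small, 6 on the higher side and 16 on the lower, were left out. They included the smallest adjusted p after Gm43110 (limma, 0.0622). Of the genes named on the higher side, the pituitary hormones growth hormone (Gh) and prolactin (Prl) had the widest differences. Gh (chromosome 11, 106300271 to 106301865) stood at 0.25 and 1.15 TPM in WT and at 17.08 and 12.03 TPM in K823R. Its log2 difference was 3.23 with SE 0.33 (adjusted p = 0.431). Prl (chromosome 13) stood at 0 and 0.11 TPM in WT and at 3.05 and 3.56 TPM in K823R (adjusted p = 0.632). Ilvbl (chromosome 10), which encodes a thiamine-dependent lyase-family enzyme, was at 28.2 ± 0.156 TPM in WT and 53.1 ± 4.02 TPM in K823R (SD, n = 2 each; adjusted p = 0.431). Tle6 (chromosome 10), of a family of transcriptional corepressors, had means of 4.31 and 12.5 TPM. Pld4 (chromosome 12), of the phospholipase D family, had means of 2.34 and 6.36 TPM (adjusted p = 0.632 for each). On the lower side, Nos1ap (chromosome 1), an adaptor of neuronal nitric oxide synthase, was at 36.2 ± 14.0 TPM in WT and 8.74 ± 1.96 TPM in K823R (SD, n = 2 each; log2 difference -1.90, SE 0.30, adjusted p = 0.911). The adhesion receptor Adgra3 (chromosome 5) had means of 31.5 and 14.3 TPM. Nop58 (chromosome 1), a core protein of box C/D small nucleolar particles, had means of 27.3 and 16.7 TPM. Uxt (chromosome X) had means of 24.4 and 16.04 TPM, the respiratory complex I subunit Ndufs4 (chromosome 13) of 128 and 97.3 TPM, and the tRNA modification gene Yrdc (chromosome 4) of 26.7 and 18.0 TPM. Adjusted p values for these 5 genes ran from 0.760 to 0.918. In simulated data of the same 15390 genes and design, limma recovered 34.7% of genes changed by 2-fold and 69.3% by 4-fold. It recovered 81.8% of those changed by 8-fold and 89.0% by 16-fold. All fold sizes were changed together there, which eases the adjusted threshold. Spreads were shuffled among all genes and the noise was independent between genes. The shares therefore do not measure the power for the genes named here.

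Receptors and markers of itch-sensing neurons did not pass the test as a group. Of 28 tested members of that list, 15 were higher and 13 lower in K823R, with a median log2 difference of 0.01 (camera adjusted p = 0.441). By limma 0 members passed over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The leukotriene receptor Cysltr2 was at 10.6 ± 2.59 TPM in WT and 14.97 ± 1.89 TPM in K823R (SD, n = 2 each; adjusted p = 0.918). The receptors Mrgprb4, Mrgprb5 and Htr7, the last a serotonin receptor, had means of 11.6, 70.3 and 11.99 TPM in WT and 9.30, 61.5 and 10.005 TPM in K823R (adjusted p = 0.918 for each). The other histamine receptors, added here outside the rule for named genes, stood at 0.885 and 1.21 TPM for Hrh2 and at 4.70 and 3.65 TPM for Hrh3 (means of WT and K823R). Hrh4 was listed at 0 in every library. The list's mean of -0.01 and the direction of its test were opposite to its median. The median turned negative under upper-quartile, median-of-ratios and quantile scaling.

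**Figure D1:**
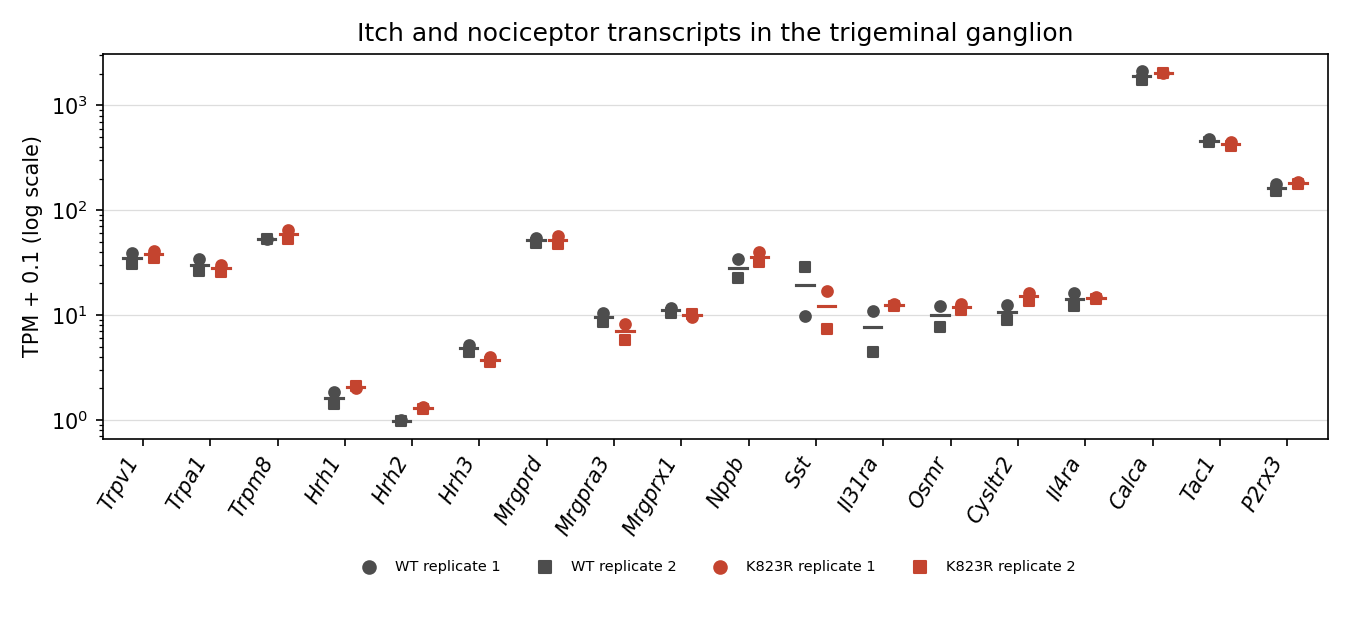
Transcript levels of itch and nociceptor genes in each library, as TPM + 0.1 on a log axis, with WT in grey and K823R in red, circles for replicate 1, squares for replicate 2 and bars for the group means. Trpv1 lay at 39.2 and 30.6 TPM in WT and 40.9 and 35.0 TPM in K823R, so the groups overlapped.

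Nociceptor classes, the TRP channel family and the SUMO pathway did not pass either, and no member of these lists passed limma over all genes or adjusted over the list alone. The 17 peptidergic nociceptor markers had a median log2 difference of -0.0026 and the 20 non-peptidergic markers one of -0.0042 (camera adjusted p = 0.704 for each). The itch-neuron receptor Mrgpra3 had means of 9.41 TPM in WT and 6.92 TPM in K823R. Among 16 TRP channels the median was 0.10 (camera adjusted p = 0.359), with -0.019 without K823R replicate 1 and 0.22 without K823R replicate 2. The medians of the peptidergic, non-peptidergic and SUMO lists also changed sign with single libraries left out. The lysosomal channel Mcoln1 had the smallest p, at 59.3 ± 0.672 TPM in WT and 81.4 ± 7.48 TPM in K823R (SD, n = 2 each; adjusted p = 0.918, and 0.0893 over the list alone). The 23 SUMO pathway genes had a median of -0.020 (camera adjusted p = 0.704). The SUMO protease Senp3 had means of 48.9 and 55.2 TPM. The 19 Trpv1 neighbours on chromosome 11 had a median of -0.0039 (camera adjusted p = 0.704). Ube2g1, with the smallest p among them, had means of 24.5 and 20.7 TPM. Large-diameter neuron markers (24 genes, median 0.01, camera adjusted p = 0.527), cold-sensing neuron markers (6 genes, 0.05, 0.440) and brain neuron markers (10 genes, 0.02, 0.843) did not pass either.

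Voltage-gated channels and activity, injury and stress genes were also short of the threshold as lists. Voltage-gated sodium channels (13 genes, median log2 difference 0.04, camera adjusted p = 0.843), calcium channels (16 genes, 0.10, 0.397) and potassium channels (36 genes, 0.05, 0.440) showed small medians. Kcnk4, the mechanosensitive potassium channel TRAAK, was at 8.87 ± 1.46 TPM in WT and 14.9 ± 0.877 TPM in K823R (SD, n = 2 each; adjusted p = 0.918, and 0.195 over the list alone). Immediate early genes (27 genes, median 0.06), nerve injury genes (20 genes, -0.0066), heat shock and chaperone genes (22 genes, 0.05) and circadian clock genes (19 genes, 0.02) each had a camera adjusted p of 0.440. The injury-induced gene Gadd45a had means of 47.7 TPM in WT and 34.8 TPM in K823R, and the clock repressor Nr1d2 had means of 36.0 and 29.6 TPM (adjusted p = 0.918 for each). The 12 mitochondrially encoded protein genes had a median of -0.06 and the 8 proliferation markers one of -0.11 (camera adjusted p = 0.704 and 0.236). Medians and means had opposite signs for the itch, circadian, SUMO, mitochondrial and erythroid lists. The test of the large-diameter list pointed down while its median and mean were above 0.

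Transcripts of oligodendrocytes and astrocytes, the glia of the central nervous system, rose as a list in K823R. Of 20 tested members 18 were higher, with a median log2 difference of 0.63 (camera with a preset correlation, adjusted p = 2.68e-06; adjusted p = 0.903 with an estimated correlation). By limma 0 members passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The neuroglycan gene Cspg5 was at 6.28 ± 0.240 TPM in WT and 9.93 ± 0.0354 TPM in K823R (SD, n = 2 each; adjusted p = 0.0718 over the list alone). Angiotensinogen (Agt) was at 6.38 ± 0.636 and 9.87 ± 0.290 TPM. Mag, a protein of both central and peripheral myelin, had means of 44.4 and 72.8 TPM, and the tight junction gene Cldn11 had means of 7.51 and 19.4 TPM. WT replicate 1 stood apart from the other 3 libraries for genes picked after their values were seen. The central myelin genes Mog and Mobp were at 0 and 2.31 TPM in it and at 9.59 to 18.0 and 113 to 178 TPM in the other libraries. The astrocyte filament gene Gfap was at 3.72 TPM against 60.3 to 71.1 TPM. Without WT replicate 1 the list's median was 0.25 and its camera adjusted p 0.0513, in a range of 3.49e-20 to 0.0513 over the alternatives with a preset correlation.

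Markers of myelinating Schwann cells, connective tissue and macrophages also rose as lists, with WT replicate 1 again the lowest library for each. Myelinating Schwann cell markers were higher in 19 of 22 members (median log2 difference 0.19, camera adjusted p = 0.00192; adjusted p = 0.911 with an estimated correlation). The myelin lipid carrier Pmp2 was at 18.5 ± 4.002 TPM in WT and 29.7 ± 2.73 TPM in K823R (SD, n = 2 each) and the myelin protein Pmp22 at means of 2852 and 3390 TPM. Fibroblast and meningeal markers were higher in 22 of 23 members (median 0.49, camera adjusted p = 1.50e-04; adjusted p = 0.903 with an estimated correlation). Mgp, an inhibitor of calcification, had means of 59.2 and 115 TPM, and the collagen gene Col1a2 of 52.0 and 67.9 TPM. In this list K823R replicate 1 was the highest library. Ptgds, picked after its values were seen, stood at 2374 TPM in it against 109, 577 and 472 TPM in the others. Macrophage markers were higher in 15 of 20 members (median 0.38, camera adjusted p = 0.00834; adjusted p = 0.911 with an estimated correlation). The complement genes C1qc and C1qa had means of 13.2 and 23.7 TPM in WT and 21.4 and 33.7 TPM in K823R. No member of these lists passed limma over all genes or adjusted over the list alone, and 2 Schwann cell, 1 fibroblast and 3 macrophage members had an unadjusted p under 0.05. Without WT replicate 1 the medians were -0.021 for the Schwann cell list, 0.20 for the fibroblast list and 0.10 for the macrophage list. Camera adjusted p was then 0.683, 0.901 and 0.822, the upper ends of ranges over the alternatives with a preset correlation that began at 3.42e-10, 1.70e-10 and 7.64e-07. Without K823R replicate 2 the Schwann cell and macrophage calls were lost as well (medians 0.09 and 0.19, camera adjusted p = 0.529 and 0.682). Without K823R replicate 1 the fibroblast median was 0.24 and the Schwann cell median 0.29. Without WT replicate 2 the medians were 0.31 for the Schwann cell list, 0.83 for the fibroblast list and 0.66 for the macrophage list. With at least 10 TPM in 2 libraries the fibroblast median was 0.27.

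**Figure D2:**
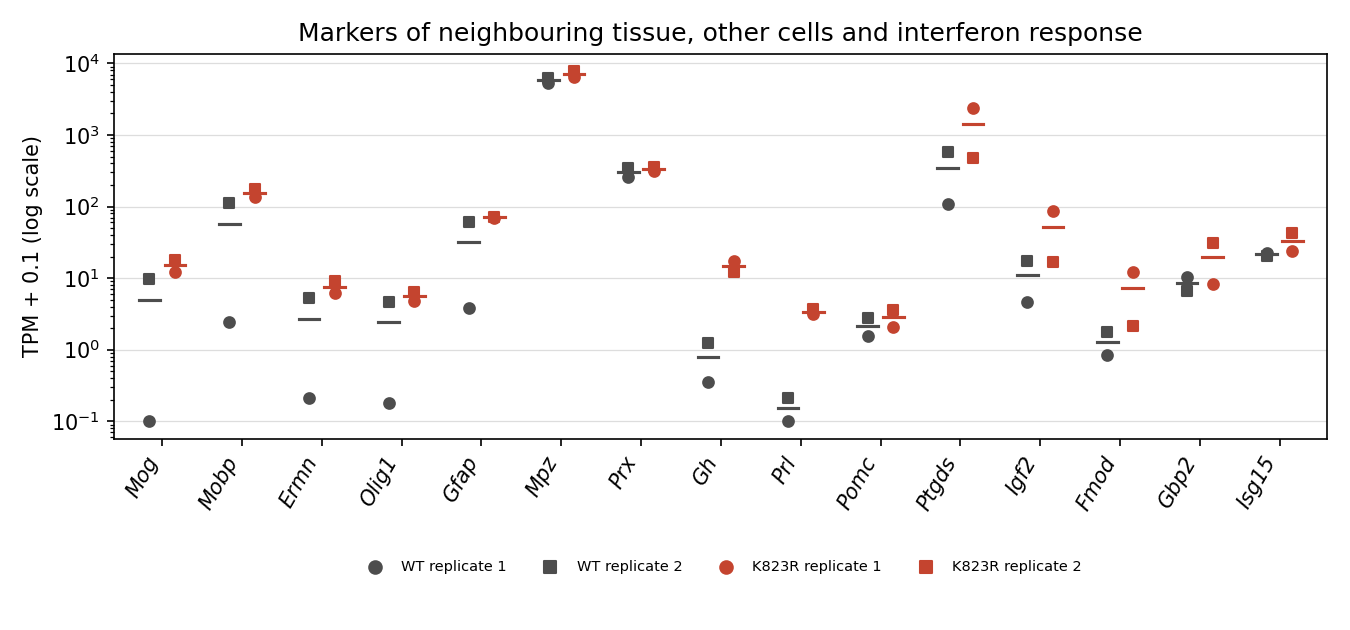
Transcript levels of markers of central glia, Schwann cells, pituitary and connective tissue and of interferon response genes in each library, as TPM + 0.1 on a log axis, with WT in grey and K823R in red, circles for replicate 1, squares for replicate 2 and bars for the group means. WT replicate 1 had the lowest value for Mog, Mobp, Ermn, Olig1 and Gfap, and K823R replicate 1 had the highest value for Ptgds, Igf2 and Fmod.

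Interferon response and cytokine transcripts rose as lists, and the interferon list was highest in a single library. Interferon response genes were higher in 26 of 28 members (median log2 difference 0.39, camera adjusted p = 2.66e-05; adjusted p = 0.903 with an estimated correlation). Bst2, which tethers budding virus to the cell surface, was at 28.1 and 22.8 TPM in WT and 38.1 and 68.6 TPM in K823R. Gbp3, an interferon-induced GTPase, was at 5.73 and 5.90 TPM in WT and 7.27 and 16.03 TPM in K823R. K823R replicate 2 had the highest list median. Without it the median was 0.11 and the camera adjusted p 0.299, in a range of 6.76e-16 to 0.299 over the alternatives with a preset correlation. The median was 0.70 without K823R replicate 1 and 0.22 without WT replicate 2. Inflammatory cytokines and chemokines were higher in 13 of 13 members (median 0.25, camera adjusted p = 0.00807; adjusted p = 0.903 with an estimated correlation). The chemokine Ccl12 was at 3.83 ± 0.566 TPM in WT and 7.54 ± 1.31 TPM in K823R (SD, n = 2 each; adjusted p = 0.0933 over the list alone), and the macrophage growth factor Il34 had means of 37.6 and 44.4 TPM. The cytokine call was lost without WT replicate 1 (median 0.17, camera adjusted p = 0.596) and without K823R replicate 2 (0.13, 0.109), in a range of 6.47e-04 to 0.596 over the alternatives with a preset correlation. With no filter on low values its median was 0.11. No member of these lists passed limma over all genes or adjusted over the list alone, and 3 interferon and 1 cytokine members had an unadjusted p under 0.05.

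Glucocorticoid-responsive genes were the single list that camera called as lower in K823R. The list's median deviation from the mean over the libraries was 0.19 in WT replicate 1 and -0.020 in WT replicate 2. In K823R it was -0.11 and -0.10. Of 17 tested members 14 were lower, with a median log2 difference of -0.20 (camera adjusted p = 1.45e-04; adjusted p = 0.903 with an estimated correlation). The transcription factor gene Zbtb16 was at 3.41 ± 0.0283 TPM in WT and 1.97 ± 0.106 TPM in K823R (SD, n = 2 each), and the kinase Sgk1 at 81.2 ± 6.57 and 68.4 ± 1.03 TPM. Arrdc2 had means of 18.4 and 12.3 TPM, and the steroid-induced factor Klf9 had means of 47.0 and 39.2 TPM. The groups did not overlap for 6 of the 17 members, against 34.0% over all genes, and fry did not call the list (fry adjusted p = 0.789). No member passed limma over all genes or adjusted over the list alone, where the smallest adjusted p was 0.240, and 3 had an unadjusted p under 0.05. Leaving out each library in turn kept the call (camera adjusted p from 2.05e-06 to 0.0464), although the median was -0.098 without WT replicate 1.

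Pituitary, mural cell and Gq signalling lists passed camera by narrower margins. The pituitary list had 6 tested members and a median log2 difference of 0.22 (camera adjusted p = 0.0141; adjusted p = 0.903 with an estimated correlation). Gh and Prl, which met the filter on low values only through K823R, were the 2 members that passed adjusted over the list alone (adjusted p = 0.00168 and 0.00207). Pcsk2, a prohormone convertase of neurons and endocrine cells, had means of 74.2 and 82.6 TPM. Mural cell markers, of pericytes and vascular smooth muscle, were higher in 9 of 15 members (median 0.19, camera adjusted p = 0.0411; adjusted p = 0.903 with an estimated correlation). The receptor Notch3, at 2.22 ± 0.325 TPM in WT and 5.18 ± 0.962 TPM in K823R, and the contractile gene Cnn1, at 0.0800 ± 0.0141 and 1.92 ± 0.523 TPM (SD, n = 2 each), passed adjusted over the list alone (adjusted p = 0.0472 for each). Cnn1 was near 0 in WT and met the filter of a mean of at least 1 TPM only through its K823R values. Acta2, smooth muscle actin, had means of 5.49 and 9.11 TPM. Gq signalling and TRPV1 modulator genes were higher in 31 of 34 members, where 57.4% of all genes tested were higher. The median was 0.07, against 0.026 over all genes (camera adjusted p = 0.0464, and 0.911 with an estimated correlation). The phospholipase Plcb3 was at 184 ± 0.255 TPM in WT and 206 ± 3.15 TPM in K823R (SD, n = 2 each; adjusted p = 0.941 over the list alone). Leaving out any one library ended the pituitary call with medians of 0.21 to 0.32 (camera adjusted p from 0.0527 to 0.0688). With no filter on low values the median was 0.035 and the adjusted p 0.144, the upper end of a range over the alternatives with a preset correlation that began at 0.00467. The mural call was lost without WT replicate 1 (median 0.14, adjusted p = 0.596) or K823R replicate 1 (0.10, 0.228), in a range of 0.0112 to 0.596 over the alternatives with a preset correlation. The Gq call was lost without WT replicate 2 (median -3.33e-04, adjusted p = 0.861), K823R replicate 1 (0.03, 0.413) or K823R replicate 2 (0.09, 0.0794), under median-of-ratios scaling (0.05, 0.0623), with 4 other rescalings or filters that left the median at 0.06 to 0.07 and with preranked camera, in a range of 0.00495 to 0.861 over the alternatives with a preset correlation. Without WT replicate 1 its median was 0.13.

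**Figure D3:**
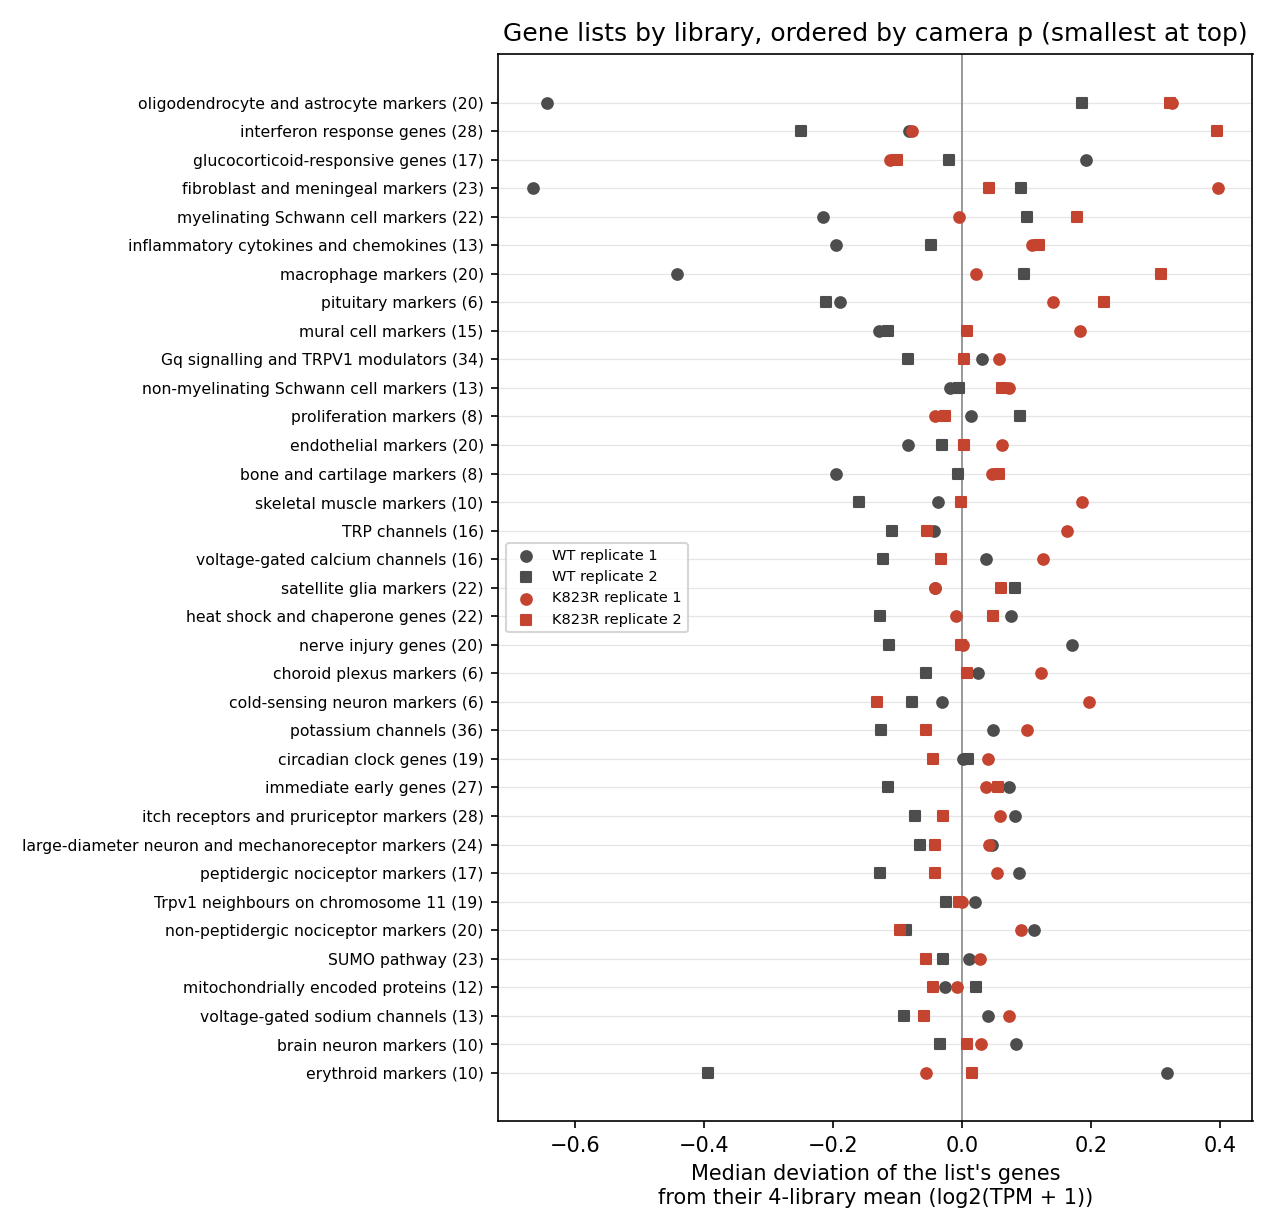
Median deviation of each gene list's members from their mean over the 4 libraries, in log2(TPM + 1), with 1 line per list and the number of tested members in brackets (WT grey, K823R red, circles replicate 1, squares replicate 2). For oligodendrocyte and astrocyte markers WT replicate 1 lay at -0.64 and the other 3 libraries between 0.19 and 0.32, and for interferon response genes K823R replicate 2 lay at 0.40 and the others between -0.25 and -0.08.

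The remaining cell type lists did not pass camera. Satellite glia markers, of the cells that wrap sensory neuron bodies, had a median log2 difference of -0.026 over 22 genes (adjusted p = 0.440). The cadherin gene Cdh19 among them had means of 36.2 TPM in WT and 29.2 TPM in K823R. Non-myelinating Schwann cell markers (13 genes, median 0.10, adjusted p = 0.216), endothelial markers (20 genes, 0.11, 0.277) and bone and cartilage markers (8 genes, 0.20, 0.343) did not pass. Skeletal muscle markers (10 genes, 0.16, 0.359), choroid plexus markers (6 genes, 0.06, 0.440) and erythroid markers (10 genes, -0.05, 0.845) did not either. Lists with fewer than 5 tested members were not tested by camera. These were T and B lymphocyte (4), neutrophil and bone marrow (4), mast cell (4), melanocyte (2) and Y-linked and X-inactivation genes (4). Of the mast cell markers, the tryptase Tpsb2 had means of 0.760 TPM in WT and 1.74 TPM in K823R, and the receptor Kit 22.0 and 21.7 TPM (limma adjusted p = 0.918 and 0.989). Across the 35 lists tested, camera with a preset correlation called 10 and camera with an estimated correlation 0. The latter rests on 2 residual degrees of freedom and could hardly call a list. The estimated correlation was -0.0056 for the cytokine list and -0.17 for the pituitary list, both under the preset 0.01. Their adjusted p with it was still 0.903, so correlation between members does not account for those losses. The test fry, which asks whether a list's genes move one way on balance, called 1, the pituitary list (fry adjusted p = 0.0280). Among the lists camera called, the groups did not overlap for 14 of 20 oligodendrocyte and astrocyte members. The counts were 3 of 6 pituitary, 7 of 15 mural, 11 of 28 interferon and 5 of 13 cytokine members. They were 6 of 17 glucocorticoid, 8 of 23 fibroblast, 7 of 20 macrophage and 7 of 22 Schwann cell members. For the Gq list the count was 7 of 34, against 34.0% over all genes.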

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

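Scaling, filters on low values and left-out libraries were compared for each reported value. Rescalings of TPM, quantile normalization, TPM filters, treat and preranked camera were chosen after the data were seen. Count-based alternatives set beforehand (RLE, upper-quartile and library-total factors, CPM filters, DESeq2, the exact test, voom, glmTreat) were not run, because the table holds TPM. With a library left out, the lone library is assumed to vary like the other group. The causes of the moves below were not tested, except that fewer libraries or genes entered some fits. Depth is unknown and its effect was not measured. The 11 other named genes did not pass in any alternative and kept their direction.

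The count of changed genes was 1. It was 0 with TPM over nuclear protein-coding genes and with standard symbols, where Gm43110 was not among the genes tested. With no filter it was 0, and without any one library the call on Gm43110 was lost. The count was 3 with at least 1 TPM in 2 libraries (adding Gm43590 and 1 unnamed locus). It was 2 with at least 10 TPM in 2 libraries (adding Gm11007) and 4 at an adjusted p below 0.1. Unadjusted p under 0.05 held for 574 to 1111 genes when a library was left out. Libraries share only a replicate number (correlation of same-numbered within-group differences 0.05, 2 pairs), and with the replicate block 0 genes and 9 lists, all but the mural one, were called. The count of changed lists was 10. It was 6 with at least 10 TPM in 2 libraries, where the mural, pituitary and cytokine lists had too few members to test, 0 with an estimated correlation, 1 with fry, 0 with fry's mixed test and 4 to 11 when a library was left out.

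The Trpv1 difference ran from -0.048 to 0.30 and that of Hrh1 from 0.11 to 0.35 when a library was left out. The itch list's median was -0.0059 with upper-quartile, -0.012 with median-of-ratios and -0.012 with quantile scaling, -0.028 with at least 10 TPM, and -0.068 to 0.098 without a library. With at least 10 TPM the SUMO median was 0.0020 and the peptidergic one 0.025, and with no filter the latter was 0.012. Without a library, medians ran from -0.048 to 0.060 (peptidergic), -0.067 to 0.027 (SUMO), -0.092 to 0.10 (non-peptidergic), -0.019 to 0.22 (TRP channels), -0.021 to 0.31 (myelinating Schwann) and -3.33e-04 to 0.13 (Gq).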

Other observations

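All tests in this part were chosen after the results were seen, except the search for near-identical copies, whose prediction was written before, and the gene and list tests between the genotypes with all libraries or without one, which were planned.

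Among pathways from the annotation in the deposited table, those of the ribosome and oxidative phosphorylation shifted down and those of glycolysis, the lysosome and complement shifted up, by small medians. Pathways of the annotation's numbered series for human diseases were left out before testing. Disease pathways numbered outside that series stayed in, among them non-alcoholic fatty liver disease, which was called (camera adjusted p = 0.00347). Of the 236 others with 10 to 300 tested genes, camera with a preset correlation called 17 between the genotypes. It called 3 in each of the other pairings of the libraries. With an estimated correlation camera called 0 (adjusted p = 0.982 for the ribosome, oxidative phosphorylation, glycolysis, lysosome and complement pathways), and fry called 0. In that form camera rests on 2 residual degrees of freedom and could hardly call a pathway. Over all genes tested 57.4% were higher in K823R (median log2 difference 0.026). For the sets below, camera without a library was read by its unadjusted p at 0.05, a looser threshold than the adjusted one over pathways. Of 79 ribosomal protein genes 71 were lower in K823R, with a median log2 difference of -0.10. Rpl34 had means of 919 TPM in WT and 779 TPM in K823R and Rps27a of 339 and 273 TPM. Without WT replicate 2, the library highest in these genes, that median was -0.019, with 47 lower and 32 higher, and camera did not call the set. Without WT replicate 1 it was -0.20. Among 35 nuclear-encoded complex I subunits of the respiratory chain 26 were lower (median -0.072; -0.12 without WT replicate 1), with Ndufa5 at means of 421 and 347 TPM. The mitochondrially encoded subunit mt-Nd4l lay the other way, at means of 372 and 589 TPM, while 8 of the 12 mitochondrially encoded protein genes were lower (median -0.06). By contrast, 56 of 69 glycolysis pathway genes were higher (median 0.12; 0.048 without WT replicate 2), with the glycolytic enzyme Eno1 at means of 551 and 622 TPM. Of 112 lysosome genes 85 were higher (median 0.093; 0.019 and not called by camera without WT replicate 2, 0.061 without K823R replicate 1). Of 48 complement and coagulation genes 38 were higher (median 0.15; 0.17 without WT replicate 1, where 38 were still higher but camera did not call the set), with the C1 inhibitor gene Serping1 at means of 107 and 130 TPM. The macrophage markers C1qc and C1qa are also members of that pathway. None of these genes passed limma over all genes. The log2 difference had a Spearman correlation of 0.124 with gene length across 8687 genes, which are not independent replicates, against -0.198 and 0.015 in the other pairings. The 1709 other genes of similar length to the ribosomal protein genes had a median of -0.012.

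The oligodendrocyte and astrocyte list had a median log2 difference of 0.63 between the genotypes. Peripheral myelin RNA is argued against for the fall in WT replicate 1, by its size against the mean of the other libraries. The 12 members found only in this list had a median of -2.16 (interquartile range -2.73 to -0.41). The 19 found only in the Schwann cell list had -0.28 (-0.40 to -0.22), and the gap was -1.88 (two-sided permutation of genes, p = 0.00014). That p treats genes as independent, although their estimated correlation was 0.69 in this list and 0.64 in the Schwann cell list. It does not measure the spread between libraries, and WT replicate 1 was picked after its values were seen. A WT library with little central nerve tissue, such as the root that enters the brainstem, is a candidate explanation, since WT replicate 1 was the lowest library for 19 of 20 members and without it the median was 0.25 (camera adjusted p = 0.0513). A genotype effect stays open, because WT replicate 2 lay below both K823R libraries for 14 of 20 members. With 1 other WT library, a library effect and a genotype effect on what remains cannot be told apart.

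Gh and Prl were at 12.03 to 17.08 and 3.05 to 3.56 TPM in the K823R libraries and at or under 1.15 and 0.11 TPM in WT. A variant on chromosome 11 linked to the Trpv1 allele and acting in cis was not tested for Gh, which lies on that chromosome. Such a variant could not act in cis on Prl, which lies on chromosome 13. Traces of pituitary, which lies beside the trigeminal ganglia, may be present in the K823R dissections. Of the 6 other pituitary genes Pomc, Cga, Tshb, Lhb, Fshb and Pou1f1, 1, Cga, was higher in both K823R libraries than in both WT libraries, and chance gives 1. The highest of these 6 reached 3.51 TPM, so they are too scarce to decide. Pituitary RNA and an effect of genotype cannot be told apart.

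At 18 loci, among them Gm43110, both libraries of one genotype were listed at 0 and both of the other stood at 2 TPM or more, 8 with WT at 0 and 10 with K823R at 0. Genotype as the cause of their number is argued against, since the other pairings of the libraries gave 24 and 27 such loci. Of the 13 with a reference transcript, 8 (61.5%) matched a near-identical transcript of another gene identifier. Among genes matched on level and length 42 of 135 (31.1%) did so (two-sided Fisher's exact p = 0.0345). The matched genes were above 0 in every library and were not matched on gene type. The test therefore cannot tell divided reads from a difference in gene type. The search did not check where the matching gene lies, so overlapping annotations of one place can count as copies. The values are consistent with reads being divided between copies in a way that differs from library to library, as a hypothesis, and 8 of the loci are processed pseudogenes. For the 5 unnamed loci no copy search was made.

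The 4 libraries can be paired in 3 ways, too few for a share under 0.05. The real pairing gave 1 changed gene and the highest other gave 1, so that 2 of the 3 pairings gave as many. It gave 10 changed lists by camera and the highest other, which set both first replicates against both second replicates, gave 11, so that 2 of the 3 gave as many. By fry the real pairing called 1 list and the same other pairing also 1.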
